A study of Salmo trutta with 72 samples.

How the data were processed

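RNA was sequenced from brain and liver of brown trout, and 3 tables of counts were used: brain and liver of the pesticide and temperature experiment, and liver of the parasite experiment. Per the labels, reads were quantified with kallisto and edgeR was used by the authors; versions and the genome build were not given in the sources used here. The deposited values are estimated counts per gene, the expected counts of a read assigner, and they were not scaled to library size: they were not negative, column sums were of the order of a library, and 34.9, 42.4 and 48.5% of the values in the brain, liver and parasite tables were whole numbers. Counts were rounded to whole numbers before testing. Rows carry NCBI gene identifiers, which were matched to the gene table of the reference assembly fSalTru1.1: 42390 of 42392 matched, and 9259 carried a symbol that is not a LOC number. Those named genes held 25.6, 29.0 and 26.95% of the counts of the 3 tables, so most counts lie in genes without a symbol, and members of the gene lists come from the named genes. Trout carry many pairs of similar gene copies, and reads may be shared between them; no positions are given, since the build behind the counts is not named. Columns were assigned to samples by tissue, temperature, concentration and replicate number, all 70 columns were used, and no pair of libraries of a group had counts as close as repeated sequencing of 1 library would give.

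Genes with low counts were removed with filterByExpr (minimum count 10, minimum total count 15) by group, and libraries were scaled by TMM factors. Each table was fitted once with all of its groups in the edgeR quasi-likelihood model (robust settings), and 15 comparisons were tested two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Reported are the log2 fold change, its standard error taken as the size of the log2 fold change over the square root of F, and CPM (counts scaled to a library total of 1 mega count, M) as mean ± SD over libraries. The interaction is the effect of concentration 5 at 15 °C minus its effect at 12 °C. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. On simulated counts with the depth and spread of each table, 100 genes were changed 2-fold and 100 others 4-fold per comparison. The changed genes had a mean above 5 CPM, so recovery at lower CPM was not measured. Genes were simulated without shared variation between fish. Of 2-fold changes edgeR recovered 83 to 92% in the 2-group comparisons of brain, 35 to 59% in those of liver and 28% in the parasite experiment. For 4-fold changes edgeR recovered 88% or more in every 2-group comparison. For the interaction it recovered 63% of 2-fold and 94% of 4-fold changes in brain, and 12% and 82% in liver.

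Gene lists were fixed before the data were examined, as were the comparisons, the tests, the first set of other analyses and the rule for named genes. A list was tested with at least 3 measured members, by limma camera on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison (39 in brain, 33 in liver, 31 in the parasite experiment). Beside it stand the count of members past the threshold over all genes, the count adjusted over the list alone, and camera with an estimated correlation. Genes that matched a list's patterns by letters alone were taken out of it once the gene symbols were known, and the lists were also tested without this removal. An exact permutation test of each list's mean log2 CPM per library was added after the data were seen.

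Named genes were, for each comparison with calls, the 10 genes with a symbol that rose and the 10 that fell with the smallest p, then up to 4 members of each list that camera called or that had a member past the threshold, and whatever their p the genes ache, cyp51, sdhc, scn8aa and vtg3, which carry names of pesticide targets or of the yolk precursor. Other names fixed in that last part matched no row and are not analysed here.

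Other analyses chosen beforehand were DESeq2 with its own size factors, RLE factors in place of TMM, no filter on low counts, the replicate number as a block, a fit of only the compared groups, and the estimated correlation for lists. Added after the data were seen were leaving out each library in turn, limma fry, lists without the removal of genes matched by letters alone, the exact permutation of list means, and the pituitary list mean as a covariate in brain. Removal of each library's trend of log2 CPM with gene length (a lowess curve) and the mean of the meninges and vessel list as a covariate had been written down to test the difference between the 2 counts of temperature in brain. Their use for lists and named genes was added after the data were seen. For each comparison 100 splits of the same libraries were drawn and refitted with the compared groups only. Total counts, in M, were 18.72 to 25.44 in brain, 7.97 to 26.48 in liver and 7.71 to 12.32 in the parasite experiment, and they limit the precision of genes at low CPM.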

Results

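The series measured gene expression by RNA sequencing in juvenile brown trout (Salmo trutta) from 2 experiments. In the first, fish were kept for 14 days at 12 or 15 °C with or without a mixture of the fungicides fluopyram and epoxiconazole, the herbicide diuron, and the insecticides chlorpyrifos and λ-cyhalothrin. Whole brain and a piece of liver were taken. At 12 °C the groups were no pesticides and concentration 5, and at 15 °C they were no pesticides, concentration 1 and concentration 5, as the labels name them. In the second, fish at 15 °C were exposed for 4 days to the myxozoan Tetracapsuloides bryosalmonae, the agent of proliferative kidney disease, and livers were taken after 44 further days in clean water, with unexposed fish as controls. The 72 samples formed 12 groups of 6, and the tables held 70 of them as columns. Replicate 3 of the brains at 12 °C with concentration 5 and replicate 1 of the brains at 15 °C with concentration 5 had no column, so those 2 groups were analysed with 5 libraries. Total counts per library, in mega counts (M), ran from 18.72 to 25.44 M in brain and from 7.71 to 12.32 M in the livers of the parasite experiment. Livers of the pesticide experiment held 19.34 to 26.48 M, apart from replicate 5 of the group at 15 °C with concentration 5, which held 7.97 M.

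Each table held 42392 genes, of which 9259 carried a symbol. After genes with low counts were removed, 34868 genes were tested in brain, 26181 in liver and 19255 in the livers of the parasite experiment. The labels file the temperature under a tag called batch and name several tanks without saying which fish shared one. A difference between 15 and 12 °C and any tank or batch effect shared by a whole group therefore cannot be told apart in these data. P-values below set a difference between groups against the variation between these samples. They take no account of variation between tanks, in the pesticide and parasite comparisons as in those of temperature.

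**Figure D1:**
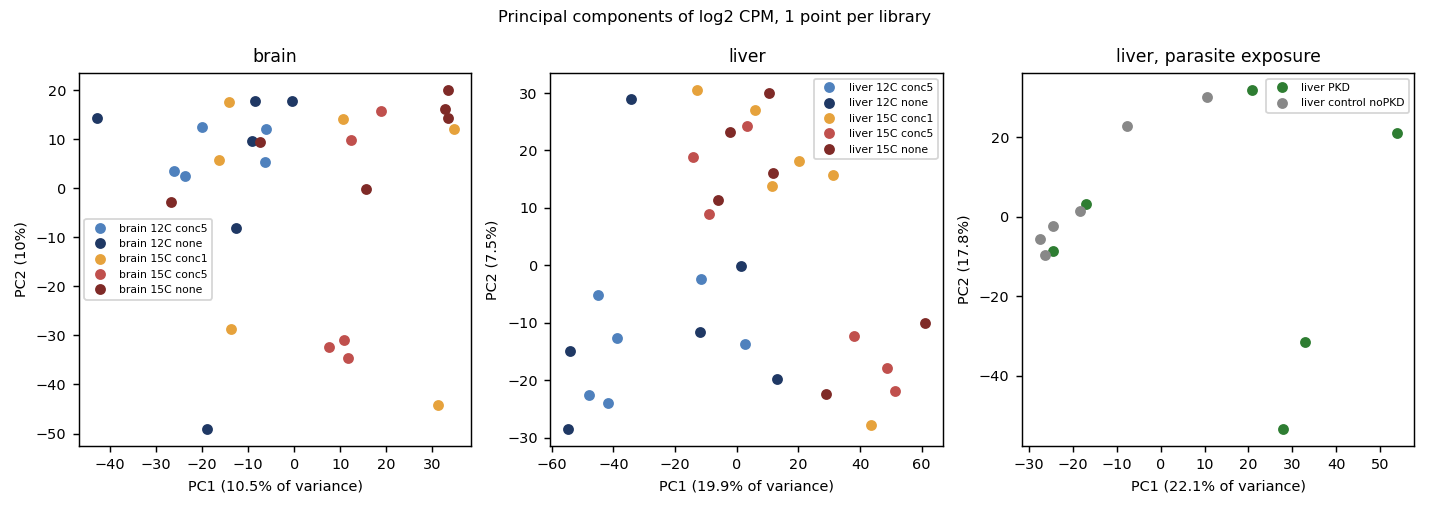
Principal components of log2 CPM (counts scaled to a library total of 1 M), 1 point per library and 1 panel per table, with the share of variance on each axis. The first 2 components held 10.5 and 10% of the variance in brain, 19.9 and 7.5% in liver, and 22.1 and 17.8% in the parasite experiment, where exposed livers ran from -24.6 to 53.7 on the first component and controls from -27.5 to 10.5.

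**Figure D2:**
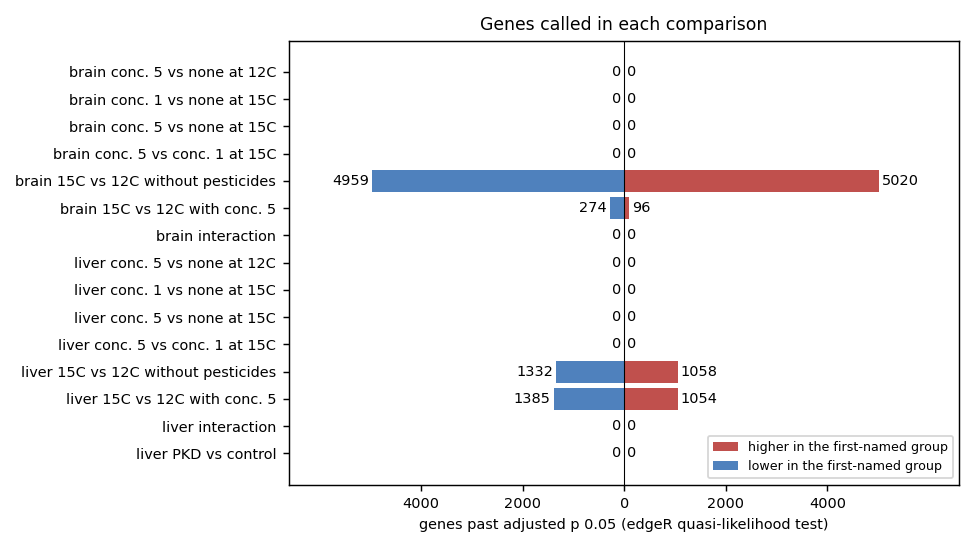
Number of genes past an adjusted p of 0.05 in each of the 15 comparisons, with genes higher in the first-named group to the right of 0 and lower ones to the left. Only the 4 comparisons of temperature have bars, from 370 genes in brains with concentration 5 to 9979 in brains without pesticides.

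The first question was how brain expression differed between 15 and 12 °C without pesticides. The U4/U6 splicing factor gene prpf31 (gene 115176592) fell from 71.6 ± 5.98 CPM at 12 °C to 44.9 ± 4.22 CPM at 15 °C (mean ± SD, n = 6 and 6, log2 change -0.67, SE 0.07, adjusted p = 1.7e-06). The SR splicing factor gene srsf2b (gene 115202364) fell from 84.5 ± 9.11 to 39.2 ± 5.24 CPM (-1.11, SE 0.12, adjusted p = 4.5e-06), and hmgb3a, a chromatin protein, fell from 498 ± 44.1 to 346 ± 16.8 CPM (-0.52, SE 0.06). Among the genes that rose were pcloa, a scaffold of the presynaptic active zone (1.06, SE 0.17), and myrf, a transcription factor of myelinating oligodendrocytes (1.68, SE 0.34). The sodium channel gene scn8aa, of the family that pyrethroids act on, rose from 13.5 ± 1.68 to 26.2 ± 6.76 CPM (0.96, SE 0.16, adjusted p = 0.00022).

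Of the gene lists fixed beforehand, 37 of 39 ribosomal protein genes fell in the brain at 15 °C without pesticides (39 when adjusted over the list alone), with a median log2 change of -0.55 and examples in rps20 (-0.92, SE 0.14) and rpl7a (-0.60, SE 0.09). The proteasome, which degrades tagged proteins, had 16 of 17 members fall (16 when adjusted over the list alone), among them psma5 (-0.51, SE 0.07) and psmb2 (-0.62, SE 0.08). Genes of the respiratory chain and ATP synthase fell in 33 of 51 cases (36 over the list alone), such as cox8a (-0.82, SE 0.12) and atp5fa1 (-0.46, SE 0.09). Sterol synthesis had 8 of 16 members fall (9 over the list alone), with idi1 at -0.77 (SE 0.13) and insig1, a brake on that pathway, at -0.45 (SE 0.10). Cell cycle and DNA replication had 12 of 42 members fall (12 over the list alone), among them cdk2 (-0.69, SE 0.15) and ccne1 (-0.69, SE 0.17). The list named for cold-inducible RNA-binding proteins held 8 SR splicing factors as measured members, of which 5 fell and 1 rose.

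In lists of cell types and structures, neuronal and synaptic genes rose in the brain at 15 °C without pesticides in 6 of 16 cases (7 over the list alone), with nlgn1, a synaptic adhesion gene, at 0.66 (SE 0.15) and shank3a, a postsynaptic scaffold, at 0.57 (SE 0.14). Myelin and oligodendrocyte genes rose in 4 of 9, including ugt8, which makes the galactolipid of myelin (1.41, SE 0.25). Markers of meninges and vessels rose in 6 of 16 (11 over the list alone), with the VEGF receptor flt1 at 1.78 (SE 0.34) and smooth muscle actin acta2 at 1.22 (SE 0.23). Extracellular matrix genes rose in 8 of 25 (11 over the list alone), with col4a2 at 2.47 (SE 0.56) and fn1a at 1.53 (SE 0.33). In camera with a preset correlation between genes the adjusted p was 3.5e-18 for ribosomal proteins, 5.7e-11 for the proteasome, 1.8e-10 for the respiratory chain, 0.00061 for sterol synthesis, 0.0070 for the cell cycle and 0.0206 for the SR factors. For the lists with a positive median it was 0.0065 for neuronal, 0.0153 for myelin, 0.0062 for meninges and vessel and 0.011 for matrix genes. None of these 10 calls held with an estimated correlation, where the adjusted p lay between 0.462 and 0.715. In an exact permutation test of each list's mean level per library, chosen after the data were seen, the adjusted p was 0.0317 for ribosomal, myelin and SR genes, 0.0281 for proteasome, sterol and neuronal genes, 0.0844 for respiratory and meninges genes, 0.162 for the cell cycle and 0.146 for matrix.

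Log2 changes in the brain without pesticides followed gene length, with a Spearman rho of 0.292 over 34867 genes (0.153 with concentration 5). Once each library's trend with length was taken out rho was 0.003 and 9069 genes passed, 7430 of them in both analyses. The lists were tested again on these values after the data were seen. Ribosomal genes fell in 32 of 39 cases (camera adjusted p = 8.5e-16), proteasome in 14 of 17 (1.8e-10) and respiratory genes in 24 of 51 with 1 higher (4.0e-07). Sterol genes fell in 8 of 16 (0.0036) and cell cycle genes in 7 of 42 (0.0319). Myelin genes rose in 5 of 9 (0.0051) and meninges and vessel genes in 6 of 16 (0.0030). The other 3 lists were no longer called: the median went from 0.34 to 0.13 for neuronal (adjusted p = 0.157), from -0.28 to -0.18 for SR (0.160) and from 0.52 to 0.34 for matrix genes (0.117). The gene shank3a did not pass (0.34, SE 0.15, adjusted p = 0.109). With an estimated correlation none of the 10 held (lowest adjusted p = 0.414).

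A second correction for the brain without pesticides took the mean of the meninges and vessel list as a covariate, and the lists were tested again in that fit too. Ribosomal genes fell in 19 of 39 cases (camera adjusted p = 1.6e-13), proteasome in 12 of 17 (1.3e-11) and respiratory genes in 6 of 51 (5.0e-06). Sterol genes fell in 7 of 16 (1.1e-06) and cell cycle genes in 8 of 42 (1.0e-06). Neuronal genes rose in 4 of 16 (4.1e-05). No longer called were SR (median -0.19, adjusted p = 0.155), myelin (0.20, 0.140) and matrix genes (-0.11, 0.500), and with an estimated correlation none held (lowest adjusted p = 0.242). The genes myrf (0.97, SE 0.33, from 1.68, SE 0.34), col4a2 (0.52, SE 0.24, from 2.47, SE 0.56) and fn1a (0.41, SE 0.18, from 1.53, SE 0.33) did not pass, each with a smaller log2 change. Smaller but still past the test were ugt8 (0.82, SE 0.20, from 1.41, SE 0.25), igf2r (0.68, SE 0.15, from 1.05) and the list's own members flt1 (0.74, SE 0.17) and acta2 (0.58, SE 0.16). The meninges and vessel list cannot be tested with its own mean in the fit.

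In total 9979 genes passed in the brain without pesticides, 5020 higher and 4959 lower at 15 °C, and 2604 passed with the meninges and vessel covariate, 2369 of them in both analyses. Over the 9979 genes that covariate took the median log2 change, in the direction of each call, from 0.50 to 0.35 and the median SE from 0.13 to 0.14. Changes above 2-fold were 1103 upward and 165 downward, and the median size of a passing log2 change was 0.50. Of the named genes 1158 were higher and 1522 lower, and the acetylcholinesterase gene ache, the target of chlorpyrifos, did not pass (286.5 ± 35.4 against 248.6 ± 16.2 CPM, adjusted p = 0.110), although it did without replicate 4 at 15 °C (adjusted p = 0.0448) and with the meninges and vessel covariate (0.36, SE 0.10, adjusted p = 0.0268). Replicate 3 at 12 °C held pituitary transcripts, with a list mean of 5.18 log2 CPM against 1.33 to 1.57 in the other 5 libraries of its group, and 9239 genes passed without it. The pituitary hormone genes prl and smtla passed as lower at 15 °C on that library alone (-9.27 and -9.80, adjusted p = 0.0312 and 0.0256), and without it their log2 changes were 4.94 and 1.60 (adjusted p = 0.781 and 0.901). Of 130 genes named by the rule 27 lost their call without some library. On the first principal component replicates 1 and 2 at 15 °C lay at -26.7 and -7.5, within the range at 12 °C (-42.8 to -0.5). Replicates 3 to 6 at 15 °C lay at 15.5 to 33.4. The count of passing genes was 11338 without replicate 1 and 7185 without replicate 4 at 15 °C.

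The same question was asked with concentration 5 in the water. The brain aldolase gene aldocb (gene 115204694) rose from 801.1 ± 39.4 to 1179 ± 92.6 CPM (mean ± SD, n = 5 and 5, log2 change 0.56, SE 0.09, adjusted p = 0.0020), and atp6v1b2, a subunit of the proton pump of synaptic vesicles and lysosomes, rose by 0.63 (SE 0.12, adjusted p = 0.0118). Among the genes that fell were the translation initiation gene eif1axb (-0.68, SE 0.10, adjusted p = 0.00060), hmgb3a (-0.40, SE 0.07, adjusted p = 0.0036) and ctcf (-0.43, SE 0.08, adjusted p = 0.0102). The dolichol kinase gene dolk fell from 43.6 ± 1.93 to 32.3 ± 0.421 CPM (-0.44, SE 0.06, adjusted p = 0.00060), and srsf2b fell by 0.74 on the log2 scale (SE 0.13). Few list members passed over all genes: 2 of 42 in the cell cycle (ccne2, -1.28, SE 0.31, and rrm2, -0.69, SE 0.18), 1 of 17 in the proteasome (psma5, -0.36, SE 0.08) and 1 of 51 in the respiratory chain (atp5l, -0.51, SE 0.11). Sterol synthesis had 0 of 16 over all genes in edgeR but 8 lower when adjusted over the list alone, with fdft1 at -0.68 (SE 0.17, adjusted p = 0.0528, and 0.0111 in DESeq2). Adjusted over the list alone 14 cell cycle, 10 proteasome and 4 respiratory genes were lower.

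Camera gave adjusted p-values of 3.0e-09 for cell cycle, 2.6e-08 for proteasome, 7.1e-07 for sterol and 1.4e-06 for respiratory genes in brains with concentration 5, all lower at 15 °C. Markers of meninges and vessels were higher (adjusted p = 0.0029, 1 member past the test, acta2, 1.01, SE 0.25), as were skeletal muscle (0.0083, 1 member, actn3b, 0.81, SE 0.18), monoamine and neuropeptide (0.0087), pituitary (0.0202) and cholinergic genes (0.0304). With an estimated correlation the adjusted p was between 0.489 and 0.621 for all 9, and the exact permutation test gave no adjusted p below 0.133. Pituitary transcripts were present in 3 of the 5 libraries at 15 °C and in 0 of the 5 at 12 °C, with list means of 3.35 ± 1.81 and 1.40 ± 0.11 log2 CPM.

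There were 370 genes past the test with concentration 5, 96 higher and 274 lower at 15 °C, and 16 and 56 of them were named. DESeq2 gave 1275, a fit of the 2 groups alone 1130, and a fit with the pituitary list mean as a covariate, added after the data were seen, 82, of which 75 were among the 370. Leaving out 1 library gave 97 to 303. At 12 °C the count was 199 without replicate 1, 97 without replicate 2 and 107 without replicate 5, and at 15 °C it was 104, 105, 177 and 208 without replicates 2, 4, 5 and 6. Of 27 genes named by the rule 15 lost their call without some library, among them psma5, atp5l, ccne2, rrm2, acta2 and actn3b. With the pituitary covariate these 6 and atp6v1b2 and ctcf no longer passed (adjusted p between 0.0507 and 0.164). Their log2 changes went from 1.01 (SE 0.254) to 1.13 (SE 0.266) for acta2, from 0.81 (0.184) to 0.79 (0.208) for actn3b, from -0.36 (0.078) to -0.35 (0.087) for psma5, and from -1.28 (0.306) to -1.23 (0.330) for ccne2. They went from -0.51 (0.105) to -0.46 (0.115) for atp5l, from -0.69 (0.175) to -0.56 (0.182) for rrm2, from 0.63 (0.120) to 0.56 (0.128) for atp6v1b2 and from -0.43 (0.079) to -0.36 (0.081) for ctcf. Each shift was smaller than the SE and each SE grew, and apart from acta2 each size fell. For acta2 the unadjusted p went from 0.00049 to 0.00025, so its call ended by the adjustment over all genes. Over the 370 genes the median log2 change, in the direction of each call, went from 0.45 to 0.43 and the median SE from 0.097 to 0.106. With the meninges and vessel covariate 243 genes passed and with the length trend removed 394 did. With that covariate acta2 (0.56, SE 0.16), rrm2 (-0.75, SE 0.19) and psma5 (-0.34, SE 0.08) did not pass (adjusted p = 0.103, 0.0571 and 0.0510), nor did rrm2 without the length trend (-0.66, SE 0.17, adjusted p = 0.0515).

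Whether the temperature difference itself changed with the pesticides was tested as an interaction. No gene passed in edgeR (smallest adjusted p = 0.169), while 4924 genes had an unadjusted p under 0.05 (3519 to 6109 without 1 library) against 1743 expected by chance, and DESeq2 called 183. Among the 183 were the pituitary genes prl (22.62 in DESeq2), smtla (21.36), smtlb (15.05) and pou1f1 (5.81). Pituitary transcripts were in 3 of 5 brains at 15 °C with concentration 5 and in 1 of 6 at 12 °C without pesticides. The interaction of scn8aa was -0.90 (SE 0.23, unadjusted p = 0.00061, adjusted p = 0.171, and 0.0451 in DESeq2), and its levels were 13.5 ± 1.68 and 26.2 ± 6.76 CPM without pesticides and 18.2 ± 2.32 and 18.98 ± 3.27 CPM with concentration 5, at 12 and 15 °C. Ribosomal protein genes had positive interaction values in 39 of 39 cases, with a median of 0.47 (rplp2 0.67, SE 0.19), and 25 passed when adjusted over the list alone. Camera gave that list an adjusted p of 7.0e-19, or adjusted p = 0.692 with an estimated correlation. Without replicate 4 at 12 °C and no pesticides, or without replicate 6 at 15 °C and concentration 5, 1 gene passed. The genes that passed at both exposures numbered 56 higher and 218 lower at 15 °C, against 14 and 39 expected if the calls were independent, and 0 went in opposite directions. Among the 9979 genes called without pesticides 85.1% had the same sign with concentration 5, where their median size was 0.19 in place of 0.50. These genes were selected for passing without pesticides, which raises the first size, and they are not independent of each other. Over all genes the Pearson r of the log2 changes at the 2 exposures was 0.16. Extreme values weigh heavily in this r, among them those of prl and smtla, which follow the libraries with pituitary transcripts. How far they moved it was not measured.

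**Figure D3:**
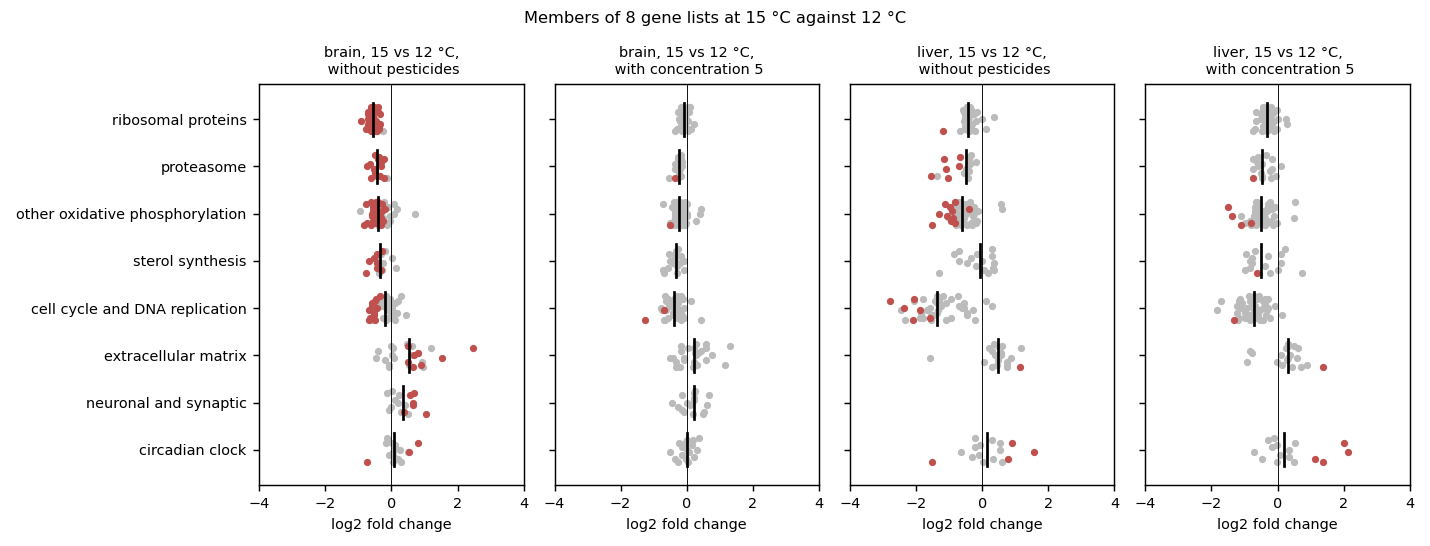
Log2 fold change between 15 and 12 °C of the measured members of 8 gene lists, in brain and liver, without pesticides and with concentration 5. Each point is a gene, red where its adjusted p was under 0.05 and grey otherwise, and the black bar is the list's median, which for ribosomal proteins was -0.55 in brain without pesticides.

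In liver, too, expression was compared between 15 and 12 °C without pesticides. The soluble epoxide hydrolase gene ephx2 (gene 115172954) rose from 3.06 ± 1.57 to 16.6 ± 8.21 CPM (mean ± SD, n = 6 and 6, log2 change 2.45, SE 0.37, adjusted p = 0.0013), and pank1a, the first enzyme of coenzyme A synthesis, rose by 2.42 (SE 0.40, adjusted p = 0.0021). Among the genes that fell were gtf2b, which codes for the general transcription factor TFIIB (gene 115170006), from 12.5 ± 2.86 to 4.74 ± 1.27 CPM (-1.40, SE 0.21, adjusted p = 0.0013), and rsl1d1, a nucleolar protein (-1.72, SE 0.29). The Mediator kinase gene cdk8 fell by 1.98 on the log2 scale (SE 0.36) and the mitotic ubiquitin-conjugating enzyme gene ube2c by 2.08 (SE 0.39). The growth factor receptor gene igf2r rose by 1.05 (SE 0.25).

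Among the lists, 11 of 52 respiratory chain genes fell in the liver without pesticides (32 when adjusted over the list alone, with 1 higher), including atp5l (-1.52, SE 0.34) and ndufb3 (-1.06, SE 0.25). Cell cycle genes fell in 6 of 42 cases (19 over the list alone), with a list median of -1.37, and proteasome genes in 6 of 17 (10 over the list alone), among them psma6a (-1.03, SE 0.19) and psmb2 (-1.16, SE 0.26). Of 39 ribosomal protein genes 1 fell, rpl36a (-1.20, SE 0.28), and the list median was -0.42. Genes of the antioxidant response fell in 5 of 14 cases and rose in 1, and both subunits of the enzyme that limits glutathione synthesis, gclm (-1.52, SE 0.38) and gclc (-1.14, SE 0.31), were among those that fell. Of the SR splicing factors srsf5a (-0.85, SE 0.20) and srsf3b (-0.99, SE 0.23) fell and srsf2a rose (0.59, SE 0.16). In the matrix list 1 of 19 rose, col4a2 (1.15, SE 0.24). A trend of the log2 changes with gene length, as seen in brain, was neither measured nor taken out in liver.

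Camera called these 7 lists, with adjusted p-values of 5.9e-13 for respiratory, 6.9e-10 for cell cycle, 1.5e-08 for proteasome, 2.4e-07 for ribosomal, 0.0052 for matrix, 0.0104 for antioxidant and 0.0424 for SR genes. None held with an estimated correlation (adjusted p between 0.574 and 0.592) or in the exact permutation test of list means (lowest adjusted p 0.0714). In total 2390 genes passed, 1058 higher and 1332 lower at 15 °C, with a median size of 1.05, and 274 and 423 of them were named. The count was 790 with only the 2 groups in the fit, where gclm, gclc, srsf2a and col4a2 no longer passed (adjusted p = 0.0517, 0.0782, 0.0824 and 0.0517). Without 1 library it ran from 778 to 2800, with 849 and 778 without replicates 3 and 4 at 12 °C and 1571, 901 and 846 without replicates 3, 4 and 6 at 15 °C. Of 60 genes named by the rule 25 lost their call without some library, gclc and srsf2a among them.

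With concentration 5, 4 of 16 clock list members passed in liver, and all 4 rose at 15 °C. They were ciartb (gene 115203577; 2.14, SE 0.40, adjusted p = 0.0034), per3 (2.00, SE 0.40, adjusted p = 0.0047), rorca (1.38, SE 0.24, adjusted p = 0.0022) and nfil3 (1.13, SE 0.25, adjusted p = 0.0079), and per3 was at 11.6 ± 3.29 CPM against 2.90 ± 2.31 (mean ± SD, n = 6 and 6). The plasma protein genes hpxa, coding for the heme carrier hemopexin (1.19, SE 0.24), cp, coding for the copper carrier ceruloplasmin (0.79, SE 0.19), and fgb, coding for fibrinogen beta (0.82, SE 0.22), rose as 3 of 9 acute phase genes. The gene of TFIIB, gtf2b, fell from 13.7 ± 4.00 to 4.35 ± 0.899 CPM (-1.66, SE 0.22, adjusted p = 0.00036), as did fbl (-1.74, SE 0.32), rsl1d1 (-1.75, SE 0.29) and tsfm (-1.71, SE 0.30).

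Respiratory chain genes fell in 4 of 52 cases in liver with concentration 5 (4 over the list alone), including ndufaf1 (-1.11, SE 0.24) and atp5l (-1.37, SE 0.34). Single members fell in the interferon list (isg20, -1.23, SE 0.31, of 17), the proteasome (psma6a, -0.73, SE 0.19, of 17, and 8 over the list alone), the cell cycle (ube2c, -1.32, SE 0.38, of 42) and sterol synthesis (pmvk, -0.62, SE 0.19, of 16). In the ER stress list dnajc3a (-2.07, SE 0.57) and edem1 (-0.89, SE 0.27) fell and ern1 (0.66, SE 0.21) rose, of 15 members, and 0 of 39 ribosomal genes passed in edgeR. Of T and NK cell genes 2 of 13 rose, lat (0.83, SE 0.22) and eomesa (1.25, SE 0.35). Of complement genes 2 of 15 rose, cfi (0.65, SE 0.21) and c7b (4.54, SE 1.06), and c7b rested on replicate 4 at 15 °C, since without it the log2 change was 0.68 (adjusted p = 0.437).

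Camera called 11 lists here, with adjusted p-values of 1.2e-07 for respiratory, 5.4e-05 for cell cycle, 0.00053 for proteasome, 0.0084 for acute phase and for ribosomal, 0.0088 for sterol, 0.0141 for complement, 0.0200 for T and NK cell, 0.0245 for interferon, and 0.0391 for clock and for ER stress genes. With an estimated correlation none held (adjusted p between 0.591 and 0.737). In the exact permutation test the adjusted p was 0.0238 for the respiratory list (3.94 ± 0.17 against 4.45 ± 0.17 mean log2 CPM), the clock list (2.48 ± 0.11 against 2.06 ± 0.18) and the interferon list (2.23 ± 0.15 against 2.70 ± 0.28), each at an unadjusted p of 0.00217, the smallest that 6 against 6 libraries can give. For the other 8 lists it was 0.0714 or higher. In total 2439 genes passed, 1054 higher and 1385 lower, with a median size of 1.02. The count ran from 1248 to 3006 without 1 library, and it was 1345, 1248, 1405 and 1612 without replicates 1, 2, 5 and 6 at 12 °C and 1307 and 1323 without replicates 1 and 4 at 15 °C. Without replicate 5 at 15 °C, the library of 7.97 M, it was 1629. Of 63 genes named by the rule 30 lost their call without some library, among them fgb, cfi, lat, eomesa, ube2c, dnajc3a, edem1, ern1 and pmvk. With only the 2 groups in the fit fgb, c7b, cfi, lat, eomesa, ern1 and pmvk did not pass (adjusted p between 0.0512 and 0.0726).

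The liver interaction of temperature and concentration 5 had 0 genes past the test in edgeR, 1077 at unadjusted p under 0.05 (841 to 1515 without 1 library) against 1309 expected by chance, and 5 in DESeq2. Camera called 8 lists on it, with the SR splicing factors at a median of 0.37 (srsf5a 0.85, SE 0.28; adjusted p = 0.0096, or adjusted p = 0.249 with an estimated correlation) and the interferon list at -0.33 (irf3 -1.18, SE 0.42; adjusted p = 0.0096, or adjusted p = 0.706 with an estimated correlation). The other 6 had estimated-correlation adjusted p-values of 0.706 to 0.789. Of the genes called at both exposures 332 were higher and 614 lower at 15 °C, against 43 and 70 expected if independent, and 2 went in opposite directions. Of those called without pesticides 97% had the same sign with concentration 5, at a median size of 0.76 in place of 1.05, again for genes selected for passing without pesticides. Over all genes the Pearson r was 0.56. On simulated counts edgeR recovered 12% of 2-fold and 82% of 4-fold changes in this interaction, so its 0 genes leave 2-fold differences open.

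Brain and liver were set side by side over the 25229 genes tested in both. Without pesticides 577 genes rose and 818 fell at 15 °C in both tissues, against 145 and 227 expected if independent, and 15 went in opposite directions. The kinase gene cdk8 was among those that fell in both (-0.53, SE 0.06, in brain and -1.98, SE 0.36, in liver), as was the proteasome gene psmb2 (-0.62 and -1.16), and igf2r rose in both (1.05 in each, or 0.68 in brain with the meninges and vessel covariate). With concentration 5 the shared genes were 12 higher and 87 lower, against 3 and 14 expected, and 1 went in opposite directions. Both tissues are from the same experiment and may come from the same fish and tanks. A fish or tank difference would then enter both, so the overlap is no independent repeat. The trend with gene length was not measured in liver, so its part in the overlap is not known.

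The effect of the mixture on the brain was asked at each temperature, and no gene passed in edgeR in any of the 4 comparisons. The gene of acetylcholinesterase, which chlorpyrifos inhibits, was at 241.5 ± 13.2 CPM with concentration 5 and 248.6 ± 16.2 without pesticides at 12 °C (mean ± SD, n = 5 and 6, log2 change of ache -0.04, SE 0.10). The sodium channel gene scn8aa, of the pyrethroid target family, was at 18.2 ± 2.32 against 13.5 ± 1.68 CPM (0.44, SE 0.16, adjusted p = 0.830), and cyp51, the sterol demethylase that epoxiconazole inhibits in fungi, at 50.6 ± 6.32 against 48.4 ± 8.03 CPM (0.06, SE 0.14). All 39 ribosomal protein genes had negative values, with a median of -0.20 (rplp2 -0.38, SE 0.13), and 22 of 29 monoamine and neuropeptide genes did (htr2cl1 -0.48, SE 0.18). Camera gave these lists adjusted p-values of 5.3e-10 and 0.0187, or adjusted p = 0.956 and 0.880 with an estimated correlation. At 12 °C 2000 genes had an unadjusted p under 0.05 (1581 to 2533 without 1 library) against 1743 expected, and DESeq2 called 15.

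At 15 °C and concentration 1 the ribosomal protein genes lay the other way, with 39 of 39 positive values and a median of 0.17 (rpl37a 0.29, SE 0.12, n = 6 and 6). The 6 unexposed brains here also enter the comparison of concentration 5 at 15 °C, the temperature comparison without pesticides and the interaction. A shift of that group would enter each of these, so lists called in several of them are no repeat of each other. Respiratory chain genes had a median of 0.13 and proteasome genes of 0.09, and matrix genes a median of -0.26 (col6a1 -0.44, SE 0.16). Pituitary genes had a median of 0.87, with list means of 2.58 ± 2.10 against 1.37 ± 0.24 log2 CPM, and 2 of the 6 exposed libraries and 0 of the 6 others held pituitary transcripts. The gene ache was at 268.3 ± 42.1 against 286.5 ± 35.4 CPM and scn8aa at 22.5 ± 5.42 against 26.2 ± 6.76 CPM. Camera gave adjusted p-values of 1.3e-11, 1.6e-05, 0.0015, 0.0015 and 0.0402 for these 5 lists in the order given, and adjusted p = 0.881 for each with an estimated correlation. In edgeR 0 genes passed and 1206 had an unadjusted p under 0.05 against 1743 expected, and DESeq2 called 9. Without 1 library the 1206 became 871 to 2202, and it lay above 1743 without replicate 1 of the unexposed group (2202) or replicate 5 of the exposed group (1876).

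At 15 °C and concentration 5 the list of genes that respond to glucocorticoids had a mean level of 3.57 ± 0.10 against 3.91 ± 0.16 log2 CPM (mean ± SD, n = 5 and 6, 6 of 7 members negative), with hsd11b2, which inactivates cortisol, at 2.91 ± 1.24 against 6.82 ± 3.71 CPM (-1.23, SE 0.34, unadjusted p = 0.0013, adjusted p = 0.423) and cry2 at -0.37 (SE 0.15). Ribosomal genes had a median of 0.27 (39 of 39 positive, rpl37a 0.49, SE 0.13), respiratory genes of 0.17 and proteasome genes of 0.14. Monoamine and neuropeptide genes had a median of 0.27, with vip at 0.89 (SE 0.25) and adcyap1a at 0.53 (SE 0.15), myelin genes of -0.21 (ugt8 -0.61, SE 0.26) and matrix genes of -0.38 (col6a1 -0.50, SE 0.17). Markers of other tissues differed with the group: pituitary transcripts were present in 3 of 5 exposed and 0 of 6 unexposed brains (list median 1.01), and skeletal muscle genes had a median of 0.57, with replicate 2 of the exposed brains at a list mean of 3.32 log2 CPM against 1.30 to 1.74 in the others. The gene ache was at 297.6 ± 38.9 against 286.5 ± 35.4 CPM (0.06, SE 0.10), scn8aa at 18.98 ± 3.27 against 26.2 ± 6.76 CPM (-0.47, SE 0.16, adjusted p = 0.461) and cyp51 at 44.2 ± 8.77 against 49.4 ± 6.71 CPM.

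For concentration 5 at 15 °C camera called 9 lists, with adjusted p-values of 5.6e-17 for ribosomal, 5.6e-06 for respiratory, 0.00014 for proteasome, 0.00023 for monoamine and neuropeptide, 0.00036 for pituitary, 0.0032 for matrix, 0.0139 for glucocorticoid and for myelin and 0.0205 for muscle genes. With an estimated correlation the glucocorticoid list had adjusted p = 0.200 and the other 8 adjusted p = 0.545, and the exact permutation test gave that list p = 0.00649 (adjusted p = 0.253 over 39 lists). In edgeR 0 genes passed (smallest adjusted p = 0.0677), 3500 had an unadjusted p under 0.05 against 1743 expected, and DESeq2 called 27. The 3500 rested in part on single libraries: it was 1903 without replicate 4 of the exposed group, 2198 without replicate 4 and 5283 without replicate 1 of the unexposed group. Without the filter on low counts edgeR called 2, with the pituitary covariate 1, and without replicates 5 and 6 of the exposed group 3 and 2.

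Between concentrations 5 and 1 at 15 °C, a comparison that shares its 5 libraries of concentration 5 with the one before and so is no repeat of it, the glucocorticoid list was lower in the brain, at 3.57 ± 0.10 against 3.93 ± 0.11 log2 CPM (mean ± SD, n = 5 and 6), with hsd11b2 at -0.97 (SE 0.34) and fkbp5, a cortisol-induced co-chaperone, at -0.98 (SE 0.38). Every library at concentration 5 lay below every library at concentration 1 on that list (exact permutation p = 0.00217, the smallest possible, adjusted p = 0.0844). Interferon-stimulated genes had a median of 0.15 (isg15 1.12, SE 0.28, adjusted p = 0.973), ribosomal genes of 0.11, cholinergic genes of 0.21 (ache 0.15, SE 0.10), monoamine and neuropeptide genes of 0.22 and muscle genes of 0.40. Camera adjusted p-values were 0.0114 for glucocorticoid and for interferon genes, 0.00041 for ribosomal, 0.0061 for cholinergic, 0.00047 for monoamine and 0.0058 for muscle genes, and with an estimated correlation the lowest was adjusted p = 0.138, for the glucocorticoid list. In edgeR 0 genes passed, 1610 had an unadjusted p under 0.05 (1148 to 2423 without 1 library) against 1743 expected, and DESeq2 called 7. Without the filter 1 passed, and without replicates 5 or 6 at concentration 5, 2 did.

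In liver no gene passed in edgeR in any of the 4 comparisons of pesticide exposure. At 12 °C cyp51 was at 105.5 ± 22.0 CPM with concentration 5 and 104.4 ± 34.7 CPM without pesticides (mean ± SD, n = 6 and 6, log2 change 0.02, SE 0.59), and sdhc, a subunit of the succinate dehydrogenase that fluopyram inhibits, at 13.2 ± 2.75 against 14.9 ± 4.73 CPM (-0.18, SE 0.22). The yolk precursor gene vtg3 was at 0.842 ± 0.543 against 5.37 ± 5.16 CPM (-2.66, SE 0.96, unadjusted p = 0.0097, adjusted p = 1). At 15 °C it lay the other way, at 6.79 ± 2.498 CPM with concentration 1 and 4.58 ± 6.32 with concentration 5 against 2.10 ± 2.73 without pesticides (1.67, SE 0.90, adjusted p = 1.00, and 1.09, SE 0.90, adjusted p = 0.980). The interaction was 3.75 (SE 1.31, unadjusted p = 0.0080, adjusted p = 0.999). Without replicate 1 of concentration 5, at 16.8 CPM, the value for concentration 5 at 15 °C was -0.04. For concentration 5 at 12 °C camera called 0 lists, and 687 genes had an unadjusted p under 0.05 (590 to 1159 without 1 library) against 1309 expected, with 2 called by DESeq2. Between concentrations 5 and 1 at 15 °C cyp51 was at 113.0 ± 95.7 against 96.5 ± 71.02 CPM, 0 lists were called, 1346 genes had an unadjusted p under 0.05 (1123 to 1576 without 1 library) and DESeq2 called 12, while edgeR called 1 without replicate 1, 5 or 6 at concentration 5.

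At 15 °C livers with concentration 1 had lower values for the ER stress list, with a median of -0.37, 15 of 15 members negative and the chaperone genes hspa5 at 158 ± 57.4 against 378.1 ± 389.6 CPM (mean ± SD, n = 6 and 6, -1.26, SE 0.57, adjusted p = 1.00) and canx at -0.63 (SE 0.29). Cell cycle genes had a median of 0.35 (ube2c 0.86, SE 0.38), complement genes of 0.14 (c4b 0.48, SE 0.22), ribosomal genes of 0.21 and matrix genes of -0.25. Camera adjusted p-values were 0.0020, 0.0038, 0.0114, 1.5e-05 and 0.0193 in that order, or adjusted p between 0.666 and 0.832 with an estimated correlation. The gene cyp51 was at 96.5 ± 71.02 against 128.5 ± 73.1 CPM. In edgeR 0 genes passed, 935 had an unadjusted p under 0.05 (704 to 1453 without 1 library, the highest without replicate 1 of the unexposed group) against 1309 expected, and DESeq2 called 3.

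With concentration 5 at 15 °C the 8 SR splicing factors all had positive values in liver, with a median of 0.26 and srsf5a at 18.3 ± 4.96 against 12.09 ± 2.98 CPM (mean ± SD, n = 6 and 6, 0.59, SE 0.20, adjusted p = 0.811). Matrix genes had a median of -0.33, with col4a2 at -0.62 (SE 0.23) and col1a1b at -0.53 (SE 0.24), and ribosomal genes of 0.07. Camera adjusted p-values were 0.0188, 0.0029 and 0.0198, or adjusted p = 0.400, 0.791 and 0.793 with an estimated correlation. The 6 unexposed livers here were also those compared with concentration 1, so lists called at both concentrations are no repeat. The gene cyp51 was at 113.0 ± 95.7 against 128.5 ± 73.1 CPM and sdhc at 11.6 ± 1.89 against 12.2 ± 3.60 CPM. In edgeR 0 genes passed, 1398 had an unadjusted p under 0.05 (985 to 2080 without 1 library) against 1309 expected, and DESeq2 called 3, while edgeR called 2 without replicate 1, 5 or 6 of the exposed group.

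The last question was how liver expression differed 44 days after exposure to the parasite. The lists of interferon-stimulated, antigen processing, phagocyte and complement genes had positive medians in exposed fish. The interferon regulatory factor gene irf9 (gene 115150804), part of the complex that switches on interferon-stimulated genes, was at 22.2 ± 13.8 CPM against 6.23 ± 1.16 in controls (mean ± SD, n = 6 and 6, log2 change 1.83, SE 0.37, adjusted p = 0.413). The values were 1.86 (SE 0.39) for irf1b and 1.40 (SE 0.32) for nlrc5, the activator of MHC class I genes. All 6 exposed livers lay above all 6 controls in the mean of the interferon list, 2.81 to 3.56 against 2.41 to 2.79 log2 CPM (exact permutation p = 0.00217, the smallest possible, adjusted p = 0.0671 over 31 lists).

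In the same comparison all 11 macrophage and granulocyte genes were positive, with a median of 1.34 (9 past the test when adjusted over the list alone), and ptprc, the leukocyte antigen CD45 (1.18, SE 0.29), lcp1 (1.35, SE 0.35) and mpeg1.1 (1.54, SE 0.41) as examples. Antigen processing genes had a median of 1.20 (5 of 6 over the list alone), with the immunoproteasome subunit psmb8a at 1.93 (SE 0.52) and tapbpl at 1.49 (SE 0.40), and interferon genes of 0.47 (6 of 16 over the list alone, tap1 0.88, SE 0.26). Complement genes had a median of 0.92 (8 of 15 over the list alone), with c4b at 9164 ± 7948 against 2544 ± 951.3 CPM (1.85, SE 0.50), c1qa at 1.64 (SE 0.50), c8g at 1.07 (SE 0.33) and cfi at 1.01 (SE 0.33). ER stress genes had a median of 0.41 (hspa5 1.13, SE 0.54) and ribosomal genes of 0.29, while sterol synthesis had a median of -0.55 (msmo1 -0.73, SE 0.24) and matrix genes of -0.27 (col1a1a -0.64, SE 0.23). Erythrocyte markers had a median of 0.12.

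Camera called these 8 lists in the parasite experiment, with adjusted p-values of 1.9e-10 for macrophage and granulocyte, 4.9e-06 for antigen processing, 5.1e-06 for interferon, 0.00067 for ER stress, 0.00068 for sterol, 0.0025 for matrix, 0.0036 for ribosomal and 0.0062 for complement genes. With an estimated correlation none held, and the lowest were adjusted p = 0.126 for interferon, 0.152 for antigen processing and 0.259 for macrophage genes. Over all genes 0 passed in edgeR, 1115 had an unadjusted p under 0.05 against 963 expected, and DESeq2 called 95, 90 of them higher, among them irf9, irf1b, nlrc5, psmb8a, c4b, ptprc and mpeg1.1 (adjusted p between 0.0026 and 0.0455). Without control replicate 2 or exposed replicate 4, edgeR called 1. Without 1 library the 1115 became 909 to 1752, with 1752 and 1458 without exposed replicates 6 and 3 and 1476 without control replicate 3. Those 2 exposed livers lay at -24.6 and -16.9 on the first principal component, within the range of the controls, and the other 4 exposed livers at 20.8 to 53.7. On simulated data of the same size edgeR recovered 28% of 2-fold and 94% of 4-fold changes.

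**Figure D4:**
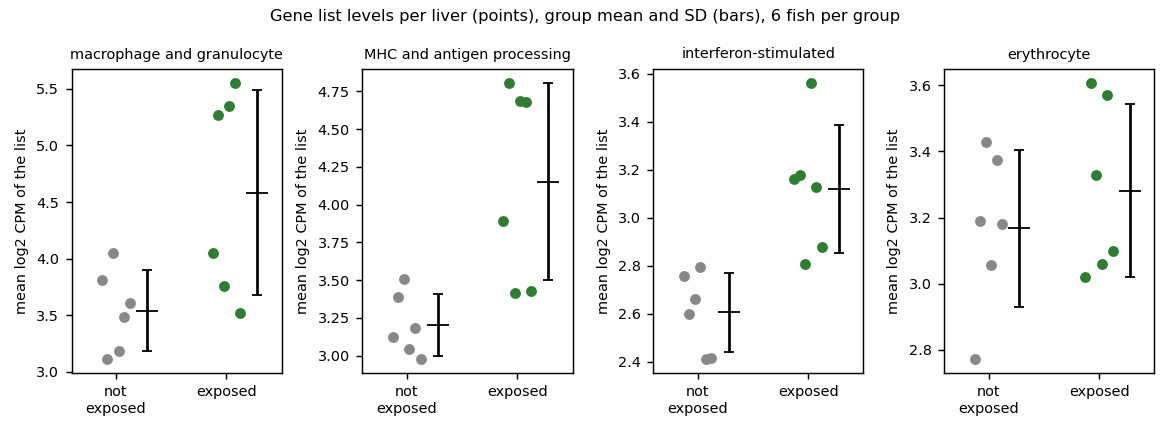
Mean log2 CPM of 4 gene lists in each liver of the parasite experiment (points, 6 fish per group), with the group mean and SD beside them. On the interferon list every exposed liver lies above every control, and the erythrocyte list is shown for blood in the samples.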

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

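The splits by genes past the adjusted p in comparisons without called genes, the draws of 5 libraries and the pituitary covariate were chosen only after the results were seen. Of 129 groups of libraries examined for single values far from the rest 14 had one, where chance gives about 1 in 20 groups, here 6.

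In brain without pesticides 9979 genes passed between 15 and 12 °C, and with concentration 5 only 370 did. The size of the gap depends on the fit: it was 7390 against 1130 with only the compared groups and 10814 against 1275 in DESeq2. A trend with gene length does not carry this gap, since 9069 against 394 genes passed after each library's trend was taken out. Vessel and meninges transcripts do not carry all of it, since 2604 against 243 passed with that list as a covariate. Whether they carry part is not decided, although that covariate took the median log2 change of the 9979 genes from 0.50 to 0.35. The list itself had a median of 0.76 between 15 and 12 °C in these brains, so the covariate overlaps with temperature. Such a drop would be seen with more of that tissue in the samples and with a temperature response of its genes alike. The 5 libraries per group do not carry all of the gap either, since 5052 was the lowest count over 20 draws of 5 from each group without pesticides. Of 100 splits of the pesticide labels 4, the real one included, gave the interaction as many genes at unadjusted p under 0.05 (5028, highest other 5756), so a different temperature response under concentration 5 may be part of it. Pituitary tissue, seen in 3 of the 5 brains at 15 °C with concentration 5, stays open: 10094 against 82 genes passed with the pituitary list as a covariate, but that covariate overlaps with temperature in the brains with concentration 5 and widened the median SE there from 0.097 to 0.106, against 0.131 before and after without pesticides, so this decides nothing. A tank shared by a group stays open too, as does the split of the brains at 15 °C without pesticides on the first principal component.

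In livers of parasite-exposed fish the macrophage and granulocyte list had a median log2 change of 1.34 while no gene passed. More blood of the same make-up in the samples is argued against, since erythrocyte markers had a median of 0.123 with an SD of 0.282 over 6 genes. These markers are of red cells only, so blood with more white cells in it stays open. A single fish is argued against too, since the lowest median with 1 exposed fish left out was 0.929, of 1.096 in the same measure. Of all 462 splits of the 12 fish 16 gave a median as large in size (highest other 1.319). More phagocytes in the exposed livers, or a higher level of these genes in each cell, could give these values, and the data do not separate them; tank sharing stays open.

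The ribosomal protein list was called in pesticide comparisons without a called gene. Of 100 splits of the brain libraries at 15 °C 71 gave that list a camera p under 0.05, and 10 gave one as small as the real split. Its genes vary together between fish of a group, which is a likely source of these calls at the preset correlation. A small shift of the whole list by the pesticides was not excluded by this test.

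For the 4 temperature counts a chance split is argued against but not excluded. Each count was reached by 1 of 100 splits, the real one, which is the least that 100 splits can give. In brain the counts were 7390 genes against a highest other of 2 without pesticides and 1130 against 5 with concentration 5. In liver they were 790 against 2 without pesticides and 2401 against 319 with concentration 5. In the 11 other comparisons the real count was 0, which all 100 splits reach whatever the cause, so this test decides nothing there. The highest others were 3, 8219, 2, 2 and 2 in brain, 3390, 132, 376, 643 and 1 in liver and 48 in the parasite experiment, in the order concentration 5 at 12 °C, concentration 1, concentration 5 and concentration 5 against 1 at 15 °C, and interaction. The splits with 8219 and 3390 genes point to a structure of the samples that the groups do not give. On the first principal component of brain a split lay within groups at 15 °C. Without pesticides replicates 1 and 2 lay at -26.7 and -7.5 and replicates 3 to 6 at 15.5 to 33.4. With concentration 1 replicates 1 to 3 lay at -16.2 to -13.6 and replicates 4 to 6 at 10.5 to 34.6. With concentration 5 all lay at 7.6 to 18.8. The cause of this split was not tested. Such a structure, if it ran along temperature, could not be told from temperature in the 4 counts. At unadjusted p under 0.05 chance was not excluded in 10 of these comparisons, since as many genes were given by 23, 60, 16 and 35 of 100 splits in brain, by 79, 58, 21, 22 and 44 in liver and by 22 in the parasite experiment, while the brain interaction, at 4 of 100, lay beyond 5 in 100.

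Camera called several lists on the interaction at the preset correlation, while an estimated correlation and fry called 0. In brain the adjusted p was 0.0020 for respiratory chain, 7.0e-19 for ribosomal, 0.0019 for proteasome, 0.00011 for monoamine and neuropeptide, 0.0151 for myelin, 0.0020 for pituitary and 0.0315 for matrix genes, and it was 0.692 or higher for each with an estimated correlation. In liver it was 0.0096 for SR splicing factors and for interferon genes, 0.0342 for ER stress, 0.0428 for sterol synthesis and for proteasome, 0.0236 for complement and for T and NK cell and 0.0290 for ribosomal genes, and 0.249 or higher with an estimated correlation.

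Single libraries lay far from their group. The liver at 15 °C with concentration 5, replicate 5, held 7.97 mega counts (M) against 20.1 to 26.4 M. The gene ache was at 2.17 CPM in liver at 12 °C with concentration 5, replicate 3 (others 0.224 to 0.769), and at 1.99 CPM in liver at 15 °C with concentration 5, replicate 5 (others 0.875 to 1.01). The gene vtg3 was at 1.99 CPM in liver at 15 °C with concentration 1, replicate 2 (others 6.80 to 8.77), and at 16.8 CPM with concentration 5, replicate 1 (others 0.376 to 5.58). It was at 7.23 CPM without pesticides at 15 °C, replicate 2 (others 0.162 to 2.68), and at 3.70 CPM in parasite control replicate 1 (others 1.32 to 1.65).

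Marker lists gave the other 7, as mean log2 CPM. The pituitary list was at 5.18 in brain at 12 °C without pesticides, replicate 3 (others 1.33 to 1.57). Retina and pineal markers were at 2.01 in replicate 6 of that group (others 0.903 to 1.13) and at 1.91 in brain at 15 °C without pesticides, replicate 3 (others 0.656 to 1.09). Muscle markers were at 3.32 in brain at 15 °C with concentration 5, replicate 2 (others 1.30 to 1.74), and astrocyte and radial glia markers at 7.24 in replicate 6 (others 7.37 to 7.40). Myelin markers were at 6.12 in brain at 15 °C with concentration 1, replicate 3 (others 6.68 to 6.94), and exocrine pancreas markers at 1.23 in liver at 15 °C without pesticides, replicate 5 (others -0.779 to -0.226).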

How the results depend on the processing

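Every gene named in these texts as past the test kept its direction in all settings tried, apart from the pituitary genes prl and smtla in brain. Every called list kept its direction in camera in the settings run for it, apart from the matrix list in brain without pesticides, the only comparison whose lists were tested with the length trend removed and with the meninges and vessel covariate. With its own mean as covariate the meninges and vessel list had a median of -0.08, which that fit largely sets. Leaving out each library, fry, the permutation of list means, the pituitary covariate and the use of the length trend and of the meninges and vessel covariate beyond the 2 counts of temperature in brain were chosen only after the data were seen. DESeq2 called genes where edgeR called 0: 15 for concentration 5 at 12 °C, 9 for concentration 1, 27 for concentration 5 at 15 °C, 7 for concentration 5 against 1 and 183 for the interaction in brain, 2, 3, 3, 12 and 5 in the same order in liver, and 95 in the parasite experiment. It gave 1275 in place of 370 between 15 and 12 °C in brain with concentration 5. With only the compared groups in the fit that count was 1130, and the liver count without pesticides was 790 in place of 2390. Without the filter on low counts edgeR called 2 genes in brain for concentration 5 at 15 °C and 1 for concentration 5 against 1, where it called 0. With the pituitary covariate these were 1 and 0, and the brain temperature count with concentration 5 was 82. With the meninges and vessel covariate the brain temperature counts were 2604 in place of 9979 without pesticides and 243 in place of 370 with concentration 5. With the length trend removed they were 9069 and 394, within 1.5 times. With the meninges and vessel covariate the matrix list had the other direction (adjusted p = 0.500). RLE factors moved no count by over 1.5 times. For these counts the cause was not tested.

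The labels give groups the same replicate numbers without saying that they mark a pair. With the number as a replicate block the brain temperature count with concentration 5 was 237 in place of 370, and no other count moved by over 1.5 times. Among named genes the block ended 5 calls and added 1 between 15 and 12 °C in brain with concentration 5. In liver with concentration 5 it ended 9 and added 3. Without pesticides it ended 2 and added 3 in brain, and ended 4 and added 3 in liver. A library correlated best with one of its own number in 4 of 28, 7 of 30 and 4 of 12 cases in the brain, liver and parasite tables, against means of 4.63, 4.88 and 1.95 over 1000 permutations of the numbers (p = 0.654, 0.234 and 0.139). Correlations above 0.1 between libraries of the same number were found in 4 of 6 pairs of brains with concentration 1 and without pesticides at 15 °C, in 3 of 6 of 2 pairs of liver groups and in 3 of 6 of the parasite experiment. These data give no evidence for pairs by number and do not exclude them.

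Over all comparisons camera called 90 lists at the preset correlation, 0 with an estimated correlation, 30 in fry, and 11 in the exact permutation of list means, which was not run for the interactions.

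With 1 library left out the counts ran as follows. In brain they were 0 to 0 for concentration 5 at 12 °C and for concentration 1, 0 to 3 for concentration 5 at 15 °C, 0 to 2 for concentration 5 against 1, 0 to 1 for the interaction, 7185 to 11338 for temperature without pesticides and 97 to 303 with concentration 5. In liver they were 0 to 2 for concentration 5 at 15 °C, 0 to 1 for concentration 5 against 1, 778 to 2800 for temperature without pesticides and 1248 to 3006 with concentration 5, and 0 for the others, and in the parasite experiment 0 to 1.

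A few log2 changes, none past the test, changed sign. In brain ache for concentration 5 at 15 °C was 0.055, ran from -0.011 to 0.093 with 1 library left out and was -0.041 with the pituitary covariate. Between 15 and 12 °C with concentration 5 scn8aa was 0.061, ran from -0.001 to 0.145 and was -0.002 with that covariate, -0.008 with the meninges and vessel covariate and -0.045 with the length trend removed. In liver cyp51 for concentration 5 at 12 °C was 0.015 and ran from -0.126 to 0.116 with 1 library left out. At 15 °C it was -0.185 for concentration 5 against none, running from -0.47 to 0.076, and 0.228 for concentration 5 against 1, running from -0.058 to 0.511. The value of sdhc for concentration 5 at 15 °C in liver was -0.069 and ran from -0.135 to 0.099. For vtg3, liver concentration 5 vs none at 15C, it was 1.085 and ran from -0.037 to 2.061.

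For prl, brain 15C vs 12C without pesticides, the log2 change was -9.27 and ran from -11.319 to 4.941 with 1 library left out. It was 2.679 with the pituitary covariate, past the test in the other direction. For smtla it was -9.802, ran from -11.843 to 1.596 and was 1.17 with that covariate. The covariate is itself a mean of pituitary transcripts and largely sets such values, so that call decides nothing. Without replicate 3 at 12 °C, which held pituitary transcripts, both prl and smtla were positive.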

Other observations

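The genes and libraries below were chosen after their values were seen, and their tests are those of DESeq2 or edgeR over all genes. In livers of parasite-exposed fish DESeq2 called 95 genes, of which 19 carried a name and 18 of these were higher. Besides interferon and phagocyte genes they held hp, which codes for the hemoglobin-binding plasma protein haptoglobin, at 3910 ± 3806 against 502.0 ± 182.9 CPM (mean ± SD, n = 6 and 6, DESeq2 log2 change 2.97, adjusted p = 0.0026; edgeR adjusted p = 0.429). Others were the immune receptor chain fcer1gl (2.52, adjusted p = 0.00027), the chemokine gene ccl19a.1 (3.14, adjusted p = 0.0028), the proteasome subunit psmb13a (2.22, adjusted p = 0.0026) and cd40, a receptor of B cells and antigen-presenting cells (1.71, adjusted p = 0.0398). Over 31 lists none had an adjusted p under 0.05 in the exact permutation test of list means.

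In brains at 15 °C with concentration 5 against none DESeq2 called 27 genes, 20 higher and 7 lower, of which 4 carried a name. These were ppp1r17, a phosphatase inhibitor gene known from Purkinje cells, at 8.80 ± 2.19 against 3.77 ± 1.33 CPM (n = 5 and 6, DESeq2 log2 change 1.23, adjusted p = 0.0065), the neuropeptide genes grp (1.76, adjusted p = 0.0214) and iapp (2.21, adjusted p = 0.0074), and the neuronal calcium sensor hpcal4 (1.09, adjusted p = 0.0393). In edgeR their adjusted p was 0.307, 0.352, 0.418 and 0.403. Levels were low for grp (1.65 ± 0.851 against 0.488 ± 0.158 CPM), iapp (1.65 ± 0.482 against 0.356 ± 0.354) and hpcal4 (3.29 ± 0.708 against 1.54 ± 0.429). Pituitary transcripts were in 3 of these 5 exposed brains and in 0 of the 6 unexposed ones.

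Pituitary transcripts split the brain libraries into 6 with a list mean of 4.40 to 5.41 log2 CPM and 22 with 0.95 to 1.62. The 6 were 3 of 5 at 15 °C with concentration 5, 2 of 6 at 15 °C with concentration 1, 1 of 6 at 12 °C without pesticides and 0 in the other 2 groups. In brain at 15 against 12 °C without pesticides, 5 of 15 growth axis genes rose (exact permutation of list means, adjusted p = 0.0317), and 3 of 12 T and NK cell genes fell (adjusted p = 0.0317), though camera did not call either list (adjusted p = 0.0593 and 0.426, or 0.462 and 0.635 with an estimated correlation). With the meninges and vessel list mean as a covariate their medians went from 0.43 to 0.14 and from -0.26 to -0.01, and 2 growth axis genes rose and 1 T and NK cell gene fell.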
